A study of Homo sapiens with 9 samples.

How the data were processed

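Expression was measured on whole-transcriptome arrays (Clariom D, human, per the file headers) in 9 samples of WPMY-1 cells, 3 each of a Neo control and of cells overexpressing the D13 or the D14 variant of ASPN. Per the labels, total RNA from stably transfected cells was labelled with biotin. Groups and replicate numbers were taken from the sample titles.

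The main values were the deposited log2 signals per transcript cluster, a group of probes that measures one transcribed locus. The submitters' processing notes name oligo, limma and the Transcriptome Analysis Console, with no role or version. A second table held log2 signals per exon or junction, made by SST-RMA with a detection call per the file headers of that deposited table. Both tables held 2995 control probe sets with identical values, so the deposited values come from the same arrays on the same scale. How clusters were summarised, the genome build and the annotation version are not given in the sources used here. Robust multi-array summaries compress large differences toward the background and the saturation end. If clusters were summarised in that way, fold changes of dim and of very bright genes may be understated, which was not tested. The columns of the exon-level table carry letter codes that the labels do not explain. They were assigned to groups but not to single samples.

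The value table held 138745 probe sets. With the 2995 controls left out, 135750 clusters remained, of which 36176 had 1 gene symbol in the platform annotation, 1119 had several and 98455 had none. Symbols were updated through a RefSeq gene table by Entrez ID for 25516 clusters and by symbol for 9899, and 761 kept the annotation's symbol. Clusters with several symbols were not named. A gene with several clusters was represented by the brightest one, by its mean over all arrays. Genes were tested where that mean was above the median over all clusters, 4.44 log2 units, and ASPN in any case. This left 23025 genes, of which 14285 were protein coding and 5956 were pseudogenes in the RefSeq table. Among the 23025 genes 74 had values identical to another gene, since one set of probes stood for both. No further normalization was applied, and the median log2 fold change of all genes was -0.0093, -0.019 and -0.0038 in D13 against Neo, D14 against Neo and D14 against D13.

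A linear model with 1 mean per group was fitted to all 9 arrays with limma (version 3.58.1, R 4.3.3), and each comparison was tested with the moderated statistic of eBayes, two-sided. The prior had 4.03 degrees of freedom beside 6 residual degrees of freedom. A gene passed where its Benjamini-Hochberg adjusted p within the comparison was below 0.05. On simulated data with the measured spread of the 23025 genes and 200 changed genes, the D13 against Neo test recovered 19% of changes of 1 log2 unit and 82% of changes of 2 log2 units, with 3 false calls among 104. The D14 against Neo test recovered 31% and 80%, with 5 false among 116, and the D14 against D13 test 14% and 81%, with 4 false among 99. In these simulated data all arrays and genes were drawn independently. The counts of false calls therefore do not hold where an array is a mixture of others.

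The 33 gene lists (matrix, signalling, immune, cell cycle, metabolic and developmental genes, and markers of other cell types), the filter, the tests, most of the alternatives and the rule for naming genes were fixed before the data were examined. Lists were tested with camera with a preset correlation of 0.01 between genes, and again with the correlation estimated per list and with fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. Adjusted p-values of lists were taken over the 33 lists of a comparison. With the estimated correlation 0 lists passed in any comparison, where 6, 11 and 4 passed with the preset correlation. With fry 0, 0 and 1 lists passed, the last being the HOX genes for D14 against D13.

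The genes named are, per comparison, the 8 with the largest positive and the 8 with the largest negative log2 fold change among those that passed and whose groups did not overlap, with small or unnamed noncoding RNA genes, pseudogenes and sex-linked markers left out of naming. ASPN was added, and for each list up to 3 members that passed or, where none passed, the 2 with the largest change. For 8 of the named genes several clusters had been measured. Their clusters gave different values for several: UBE2L6 was at -3.33 on the brighter and 0.04 on the dimmer cluster for D13 against Neo, and COL1A1 at 1.89 and -0.31 for D14 against Neo. In the same order, COL1A2 was at 2.85 and 0.10 for D14 against Neo. MCM2 was at -1.09 and -0.50 for D13 against Neo and at 1.09 and 0.33 for D14 against D13. The dimmer ERAP1 cluster, at a mean of 4.03, lay below the background control probes. Its values of 0.82, 0.21 and -0.61 for D13 against Neo, D14 against Neo and D14 against D13 were therefore not read as changes. The brighter cluster was at -1.55, -0.25 and 1.30.

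Alternatives covered normalization, the filter, the choice of clusters, the variance prior, the samples in the fit, array weights, a replicate block, stricter thresholds and leaving out each array in turn. Protein-coding genes alone, and a fit without the array of each group that lies between the other 2, were added after seeing the data. Samples with the same replicate number did not deviate together, so they were not treated as pairs. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9. Exon-level features could not be tied to genes with the tables used here, and unnamed clusters were counted but not named.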

Results

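The data were expression arrays of WPMY-1 cells, an established line of human prostate stromal fibroblasts, in 3 groups of stably transfected cells. The Neo group was the control. The D13 and D14 groups each overexpressed a variant of ASPN, the gene for asporin, a small leucine-rich proteoglycan of the extracellular matrix. D13 and D14 are names of ASPN alleles that differ in the length of a run of aspartic acid residues in the protein. Each group held 3 arrays, 9 in all, of total RNA from growing cultures that had not reached confluence. The labels call the samples of a group biological replicates but do not say whether they came from separate transfections or clones, so p-values measure only the spread between these arrays. The number of arrays limits the precision of every value. After dim genes were left out, 23025 genes were compared, and a gene is said to have risen, fallen or changed where its Benjamini-Hochberg adjusted p from limma was below 0.05. Errors of log2 fold changes are standard errors of the fit, with n = 3 arrays per group.

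Within each group, 1 array lay between the other 2 for most genes that varied. Neo replicate 3 held the middle value in 94.9% of the 534 genes whose Neo values spanned over 2 log2 units. D13 replicate 2 did so in 99.2% of 645 genes and D14 replicate 3 in 98.1% of 372 genes. Equal shares would be 33.3%, and the 27 sets of 1 array per group, a comparison added after seeing the data, gave 34.4% to 71.1% for the array most often in the middle. The outer arrays of Neo differed by over 2 log2 units in 514 genes, those of D13 in 643 and those of D14 in 366. Group means lay that far apart in 233 genes for D13 against Neo, 289 for D14 against Neo and 222 for D14 against D13. In 50 simulated data sets with no difference between groups, in which 1 array of each group was made as a mixture of the other 2, limma called 222 to 431, 220 to 388 and 216 to 398 genes in these comparisons. With 3 independent simulated arrays per group it called at most 1. Genes were drawn independently in all these data sets, so the simulated ranges here and below may be too narrow for genes that vary together. The number of called genes and of lists that passed is therefore also given without Neo replicate 3, D13 replicate 2 and D14 replicate 3, a choice made after seeing the data.

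**Figure D1:**
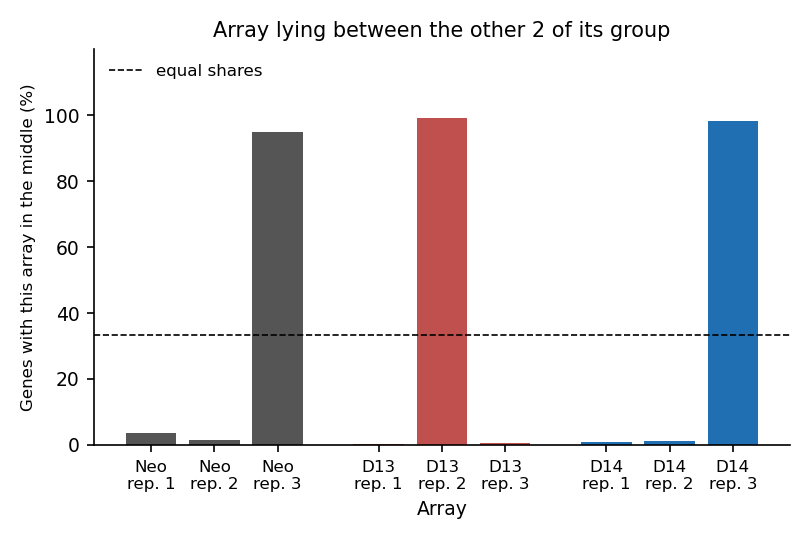
Percent of genes (vertical axis) in which each array (horizontal axis) held the middle of the 3 values of its group, among genes spanning over 2 log2 units in that group; the dashed line marks equal shares, 33.3%. Neo replicate 3, D13 replicate 2 and D14 replicate 3 reached 94.9%, 99.2% and 98.1%.

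The level of ASPN, the overexpressed gene, was measured first. Its mean signal was 4.70 ± 0.04 log2 units in Neo, 12.48 ± 0.17 in D13 and 12.82 ± 0.60 in D14 (SD, n = 3 arrays each). ASPN rose by 7.77 ± 0.28 log2 units in D13, a 219-fold difference with a limma adjusted p of 1.6e-06, and by 8.12 ± 0.28 in D14, with an adjusted p of 1.04e-06. All 6 arrays of the variants lay above the 3 Neo arrays. The variants differed from each other by 0.34 ± 0.28 log2 units, which did not pass the test (adjusted p = 0.555) and ran from 0.098 to 0.68 when 1 array was left out. Without the 3 middle arrays ASPN was higher by 7.70 ± 0.41 log2 units in D13, with an adjusted p of 0.0376, in a range from 7.70 to 7.87 when 1 array was left out. The transcript cluster that measured ASPN was TC0900010797.hg.1, and its position is not printed because the genome build was not given in the sources used here.

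**Figure D2:**
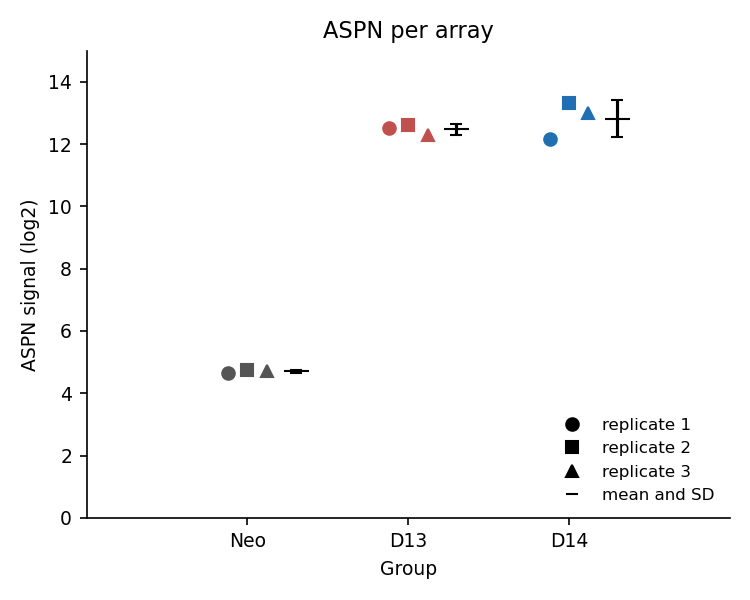
ASPN signal (vertical axis, log2) on each array of the 3 groups (horizontal axis), with symbols for the replicate number and a horizontal mark with a bar for the mean and SD of 3 arrays. The Neo mean was 4.70, and the D13 and D14 means were 12.48 and 12.82.

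The first comparison asked what differed between cells overexpressing the D13 variant and the control cells. IL1RL1, the receptor of interleukin 33, rose by 5.13 ± 0.62 log2 units in D13, from a Neo mean of 4.60, near the background control probes, so that its rise is a lower limit. Among genes of secreted and surface proteins, IGFBP7, which binds insulin-like growth factors, rose by 3.71 ± 0.40, F3, the coagulation initiator tissue factor, by 2.86 ± 0.30, ESM1, the proteoglycan endocan, by 2.86 ± 0.31, and the matrix glycoprotein tenascin C, TNC, by 2.39 ± 0.45. The immunoproteasome subunits PSMB9 and PSMB8 fell by 4.27 ± 0.67 and by 3.09 ± 0.53 log2 units. UBE2L6, the enzyme that conjugates the interferon-induced protein ISG15, fell by 3.33 ± 0.37, and the butyrophilin gene BTN3A2 fell by 3.25 ± 0.61.

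Among the other genes with the largest changes in D13, the endocytosis adaptor SGIP1 rose by 3.91 ± 0.68 log2 units, the ubiquitin ligase MARCHF3 by 3.06 ± 0.38 and the protease inhibitor SERPINB7 by 2.70 ± 0.52. TESPA1 fell by 4.15 ± 0.81, to a D13 mean of 4.14, below the background control probes at 4.32 to 4.48, so that its fall is a lower limit. Its Neo arrays lay at 6.05, 10.32 and 8.51, and Neo replicates 1 and 2 differed by more than the groups, at -4.27. The cyclic GMP phosphodiesterase PDE5A fell by 3.61 ± 0.68, the splicing regulator MBNL3 fell by 3.18 ± 0.60 and CYRIA, a regulator of Rac1, fell by 3.12 ± 0.28. The adjusted p-values of these 16 genes ran from 0.00476 for CYRIA to 0.0496 for TESPA1. In total 207 of the 23025 genes changed, 74 higher and 133 lower in D13. In each of the 207 genes the 3 arrays of one group all lay above the 3 of the other, which held for 19.6% of all genes, against 20.7% to 21.6% in the simulated data sets with mixed arrays. Without the 3 middle arrays 1 gene passed, ASPN, and none of the other genes named for D13 kept its call. The 207 genes kept their sign, which was fixed in advance because their groups did not overlap. With fewer arrays their median absolute log2 fold change went from 1.53 to 1.42 and their median standard error from 0.25 to 0.35 log2 units. Leaving out 1 array gave 69, 920 and 8 genes without Neo replicates 1, 2 and 3, 534, 3 and 89 without D13 replicates 1, 2 and 3, and 116, 90 and 26 without D14 replicates 1, 2 and 3.

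Antigen presentation genes were lower in D13 as a group. Of 21 measured members 5 fell and 0 rose, and 14 fell adjusted over the list alone. PSMB9 and PSMB8 were joined by TAP1, the peptide transporter, which fell by 2.07 ± 0.37 log2 units. The median over the list was -1.55, with a camera adjusted p of 2.28e-11 and adjusted p = 0.677 with an estimated correlation. Type I interferon response genes were also lower: of 29 members 2 fell, the viral RNA sensor IFIH1 by 2.71 ± 0.44 and PARP9 by 1.44 ± 0.26, and 11 fell adjusted over the list alone. Their median was -1.09, with a camera adjusted p of 1.61e-09 and adjusted p = 0.637 with an estimated correlation. These 2 lists passed camera without the middle arrays as well. The Neo arrays differed in both lists: Neo replicate 1 lay above Neo replicate 2 by a median of 1.23 log2 units for antigen presentation and 0.54 for the interferon response. Against Neo replicate 2 alone, D13 was at a median of -0.66 for antigen presentation, with 16 of 21 genes lower, and at -0.45 for the interferon response, with 23 of 29 genes lower.

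A further 4 lists were higher in D13 by camera with the preset correlation. Of 33 matrix glycoproteins 3 rose, IGFBP7, TNC and the basement membrane protein nidogen 2, NID2, the last by 2.39 ± 0.39 log2 units; adjusted over the list alone 5 rose and 2 fell, and camera gave an adjusted p of 0.0431, with adjusted p = 0.92 with an estimated correlation. Of 17 mesenchymal stromal cell markers the transcription factor ZEB1 rose, by 1.05 ± 0.20, over all genes and adjusted over the list alone, and camera gave 0.0141, with adjusted p = 0.835 with an estimated correlation. None of 16 HOX genes passed singly, over all genes or adjusted over the list alone. HOXB9 was at 2.11 ± 1.36, a lower limit of the difference since 1 Neo array lay below background, and HOXC8 at 1.47 ± 0.50. Camera gave 0.0211 for the HOX list, with adjusted p = 0.587 with an estimated correlation. Of 34 receptor tyrosine kinase and MAPK feedback genes KITLG, the ligand of KIT, rose by 1.88 ± 0.26 and 3 rose adjusted over the list alone; camera gave 0.0496, with adjusted p = 0.92 with an estimated correlation. Without the middle arrays these 4 lists lost their call, while their medians went from 0.25 to 0.47 for matrix glycoproteins, 0.32 to 0.35 for mesenchymal markers, 0.37 to 0.48 for HOX genes and 0.21 to 0.43 for MAPK feedback genes. D13 replicate 1 stood at the Neo level for matrix glycoproteins, at a mean deviation of -0.53 against -0.58, -0.49 and -0.31 on the Neo arrays, and for mesenchymal markers, at -0.51 against -0.65, -0.59 and -0.48, so only D13 replicates 2 and 3 were higher in these 2 lists. For HOX genes D13 replicate 3, at 0.12, lay below Neo replicate 2, at 0.23. For MAPK feedback genes Neo replicate 1 stood apart at -0.81, and Neo replicates 2 and 3, at -0.01 and -0.11, lay close to the D13 arrays, at 0.04, 0.14 and 0.10.

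Single members changed in lists that did not pass camera in D13. The replicative helicase genes MCM6 and MCM2 fell by 1.24 ± 0.20 and by 1.09 ± 0.17 log2 units, 2 of 39 DNA replication genes (camera adjusted p = 0.111), and adjusted over the list alone 1 rose and 2 fell. The p53 target AEN rose by 1.90 ± 0.31, 1 of 22 members and the same adjusted over the list alone (0.788). VEGFA, the angiogenic growth factor, rose by 1.25 ± 0.24, and MXI1, an antagonist of MYC, fell by 1.03 ± 0.19, among 29 hypoxia and glycolysis genes, with the same counts adjusted over the list alone (0.435). PLAUR, the urokinase receptor, rose by 2.29 ± 0.28 among 36 matrix proteases and inhibitors, of which 3 rose adjusted over the list alone (0.584). COL11A1 rose by 1.13 ± 0.20, a lower limit from a Neo mean near background (4.52), among 21 collagens, of which 2 rose and 2 fell adjusted over the list alone (0.545), and GADD45A, a growth arrest gene, rose by 1.79 ± 0.19 beside F3 among 28 targets of YAP/TAZ and SRF, again 2 adjusted over the list alone (0.584). The linker histone H1-3 fell by 1.39 ± 0.22 among 31 histones, of which 3 fell adjusted over the list alone (0.339). Of the TGF-beta response genes none passed, over all genes or adjusted over the list alone; INHBA was at 3.02 ± 1.19 and fibronectin, FN1, at 3.00 ± 0.92 (camera adjusted p = 0.0983). Markers of other cell types did not move as groups in D13: camera gave 0.347 for prostate epithelium, 0.711 for leukocytes, 0.719 for neurons and 0.812 for endothelium. CD68, a lysosomal protein abundant in macrophages, fell by 1.61 ± 0.31, and the epithelial acid phosphatase ACP3 was at -3.46 ± 0.69 with an adjusted p of 0.0522.

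**Figure D3:**
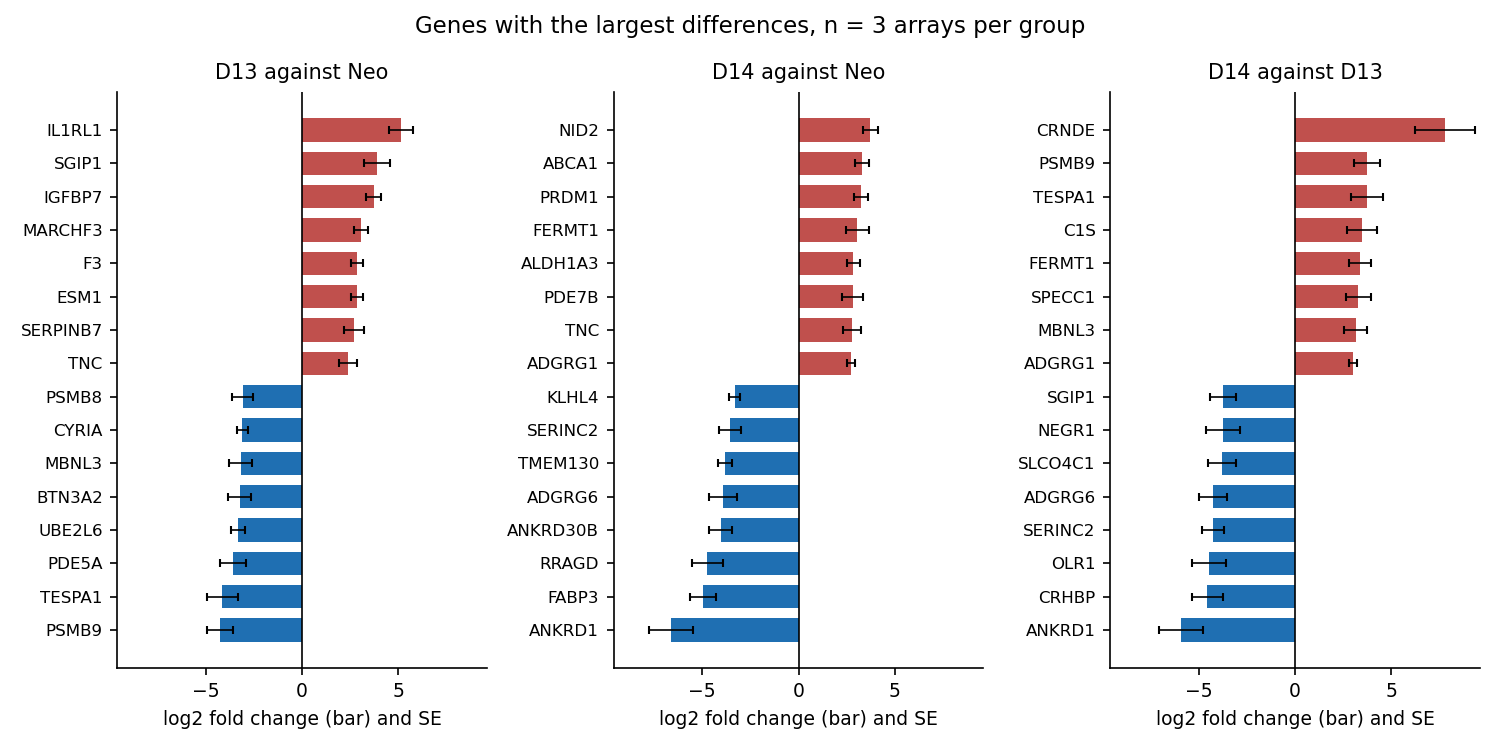
Log2 fold changes (horizontal axis; bars, with whiskers of 1 standard error, n = 3 arrays per group) of the 8 genes (vertical axis) that rose most and the 8 that fell most in each comparison, ASPN left out. IL1RL1 stood at 5.13 in D13, ANKRD1 at -6.63 in D14, and CRNDE at 7.79 for D14 against D13.

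The second comparison asked the same of the D14 variant. The matrix gene NID2 rose by 3.72 ± 0.39 log2 units in D14, TNC by 2.77 ± 0.45, the cholesterol exporter ABCA1 by 3.30 ± 0.36 and the transcriptional repressor PRDM1 by 3.25 ± 0.35. ANKRD1, a target of YAP in stromal cells, fell by 6.63 ± 1.14, from 12.2 in Neo to 5.56 in D14. The fatty acid binding protein FABP3 fell by 4.95 ± 0.68, and RRAGD, a GTPase that signals amino acids to mTORC1, fell by 4.75 ± 0.81. TAGLN, the actin-binding protein transgelin of smooth muscle, fell by 3.28 ± 0.59.

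The kindlin gene FERMT1 rose by 3.06 ± 0.59 log2 units in D14, the retinoic acid synthesis gene ALDH1A3 by 2.85 ± 0.35, the cyclic AMP phosphodiesterase PDE7B by 2.82 ± 0.55 and the adhesion receptor ADGRG1 by 2.71 ± 0.21. Another adhesion receptor, ADGRG6, fell by 3.92 ± 0.73, as did ANKRD30B by 4.05 ± 0.57. TMEM130 fell by 3.83 ± 0.37, SERINC2 fell by 3.58 ± 0.56 and KLHL4 fell by 3.32 ± 0.29. The adjusted p-values of the 16 genes with the largest changes ran from 0.00137 for ADGRG1 to 0.0475 for PDE7B. In total 247 of the 23025 genes changed, 68 higher and 179 lower in D14, and 23.7% of all genes had groups that did not overlap, against 21.1% to 22.1% in the simulated data sets with mixed arrays. Without the 3 middle arrays 1 gene passed, ASPN. The 247 genes kept their sign, which was fixed in advance because the groups did not overlap in any of them. Their median absolute log2 fold change went from 1.44 to 1.46 and their median standard error from 0.25 to 0.35 log2 units. Leaving out 1 array gave 34, 733 and 9 genes without Neo replicates 1, 2 and 3, 398, 15 and 564 without D13 replicates 1, 2 and 3, and 141, 26 and 8 without D14 replicates 1, 2 and 3.

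TGF-beta response genes were higher in D14 as a group, although the member that passed singly over all genes, TAGLN, fell. Of 28 measured members 23 had a positive log2 fold change, and adjusted over the list alone 10 rose and 2 fell. The median was 0.93, with a camera adjusted p of 5.95e-06 and adjusted p = 0.622 with an estimated correlation. D14 replicate 1 stood apart at a mean deviation of -0.11, close to Neo replicate 3 at -0.24, with D14 replicates 2 and 3 at 0.72 and 0.51. Of 36 matrix proteases and inhibitors 2 rose, PLAUR by 2.05 ± 0.28 log2 units and the procollagen protease ADAMTS2 by 1.47 ± 0.23, and adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.0336, and adjusted p = 0.632 with an estimated correlation). D14 replicate 1 lay level with Neo replicate 3 for the proteases, at -0.03 and -0.05, with D14 replicates 2 and 3 at 0.43 and 0.36. None of 21 collagens passed over all genes and 3 rose adjusted over the list alone. COL6A3 was at 3.42 ± 1.11. COL1A2 was at 2.85 ± 0.78 on its brighter cluster and at 0.10 on the dimmer. Camera gave 0.00784 for the collagens, with adjusted p = 0.426 with an estimated correlation. Matrix glycoproteins, in which NID2 and TNC rose and adjusted over the list alone 8 rose and 3 fell, reached 0.0336, with adjusted p = 0.632 with an estimated correlation; D14 replicate 1 lay at the Neo level for them, at a mean deviation of -0.32 against -0.31 on Neo replicate 3, and only D14 replicates 2 and 3 were higher, at 0.55 and 0.38. The same camera values, 0.0336 and 0.632, belonged to the 17 mesenchymal stromal cell markers, of which none passed over all genes and 2 rose adjusted over the list alone. For these D14 replicate 1 was at -0.22 and Neo replicate 3 at -0.48, with D14 replicates 2 and 3 at 0.76 and 0.60. PRRX1, a mesenchymal transcription factor, was at 7.15 ± 1.86 with an adjusted p of 0.0971, and PDGFRA at 4.28 ± 1.94.

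Genes of mitosis were lower in D14. Of 40 measured G2/M and mitosis genes 5 had a positive log2 fold change, DLGAP5, a spindle protein, fell by 0.84 ± 0.17 log2 units, and 9 fell adjusted over the list alone. The median was -0.45, with a camera adjusted p of 5.95e-06 and adjusted p = 0.622 with an estimated correlation. Within D14, replicate 1 lay above replicate 2 by a median of 0.40 over the same genes. Neo replicate 1 lay above Neo replicate 2 by 0.03. Of 29 type I interferon response genes none passed over all genes and 8 fell adjusted over the list alone; the median was -0.64, and MX1 was at -2.40 ± 0.83 and IFIT1 at -2.22 ± 0.47. Camera gave 4.61e-05 for this list, with adjusted p = 0.622 with an estimated correlation. Antigen presentation genes had a median of -1.02, with none of 21 passing over all genes and 1 higher and 2 lower adjusted over the list alone. HLA-DPA1 was at -2.58 ± 0.92, with a D14 mean of 3.74, below background. Of the Neo arrays 1 also lay below background, at 3.75, so this difference rests on the other Neo arrays. HLA-B was at -2.34 ± 1.05. Camera gave 0.000964 for antigen presentation, with adjusted p = 0.638 with an estimated correlation. Against Neo replicate 2 alone, D14 was at a median of -0.06 for the interferon response, with 15 of 29 genes lower, and at -0.26 for antigen presentation, with 13 of 21 genes lower. The groups overlapped in antigen presentation, with D14 replicate 1, at a mean deviation of 0.37, above Neo replicate 2, at -0.06.

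Further lists passed camera in D14 with few or no single members. Of 34 receptor tyrosine kinase and MAPK feedback genes KITLG and LIF, a cytokine of the interleukin 6 family, rose by 2.16 ± 0.26 and 1.22 ± 0.24 log2 units, and 6 rose adjusted over the list alone. Camera gave 0.000964 for this list, with adjusted p = 0.622 with an estimated correlation; Neo replicate 1 stood apart at -0.81, with Neo replicates 2 and 3 at -0.01 and -0.11 and the D14 arrays at 0.09, 0.27 and 0.30. None of 36 ribosomal protein genes passed, over all genes or adjusted over the list alone; RPL5 was at 0.87 ± 0.30, the median was 0.16, and camera gave 0.0208 with adjusted p = 0.632 with an estimated correlation. None of 22 p53 targets passed over all genes, 2 fell adjusted over the list alone, and CDKN1A, the cell cycle inhibitor p21, was at -1.17 ± 0.68. Camera gave 0.0336 for the p53 targets, with adjusted p = 0.638 with an estimated correlation. The groups overlapped in this list: Neo replicate 2, at -0.30, lay below D14 replicates 1 and 3, at -0.07 and -0.24, and only Neo replicates 1 and 3, at 0.55 and 0.16, were higher. Without the middle arrays 6 of the 11 lists passed, and the matrix glycoproteins, proteases, mesenchymal markers, p53 targets and ribosomal proteins lost their call. Their medians went from 0.33 to 0.14, 0.21 to 0.45, 0.15 to 0.16, -0.56 to -0.45 and 0.16 to 0.16.

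In lists that did not pass camera in D14, WNT5B rose by 2.15 ± 0.40 log2 units (24 Wnt pathway genes, camera adjusted p = 0.835), VEGFA rose by 1.34 ± 0.24 (hypoxia and glycolysis, 0.266) and the smooth muscle protein smoothelin, SMTN, rose by 1.44 ± 0.23 beside the fall of TAGLN (21 contractile genes, 0.996). ITGB8, an integrin that binds latent TGF-beta, fell by 2.02 ± 0.34 (30 integrins and adhesion molecules, 0.939), and GCLC, of glutathione synthesis, fell by 1.10 ± 0.21 (24 NRF2 targets and metallothioneins, 0.11). SDHA of respiratory complex II fell by 0.94 ± 0.19 (35 respiratory chain genes, 0.87). Adjusted over the list alone, 4 Wnt genes rose and 2 fell, 1 hypoxia gene rose, 1 contractile gene rose and 2 fell, 2 adhesion genes rose and 1 fell, 1 NRF2 target rose and 1 fell, and 1 respiratory chain gene fell. None of 17 BMP response genes passed over all genes, adjusted over the list alone 1 rose and 2 fell, and BMP4 was at -4.42 ± 1.22 with an adjusted p of 0.111. Of 14 steroid receptor and androgen response genes none passed over all genes and 2 fell adjusted over the list alone, with the progesterone receptor, PGR, at -1.33 ± 0.28 (0.399). Camera gave 0.453 for neuronal, 0.611 for prostate epithelial, 0.778 for endothelial and 0.939 for leukocyte markers.

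**Figure D4:**
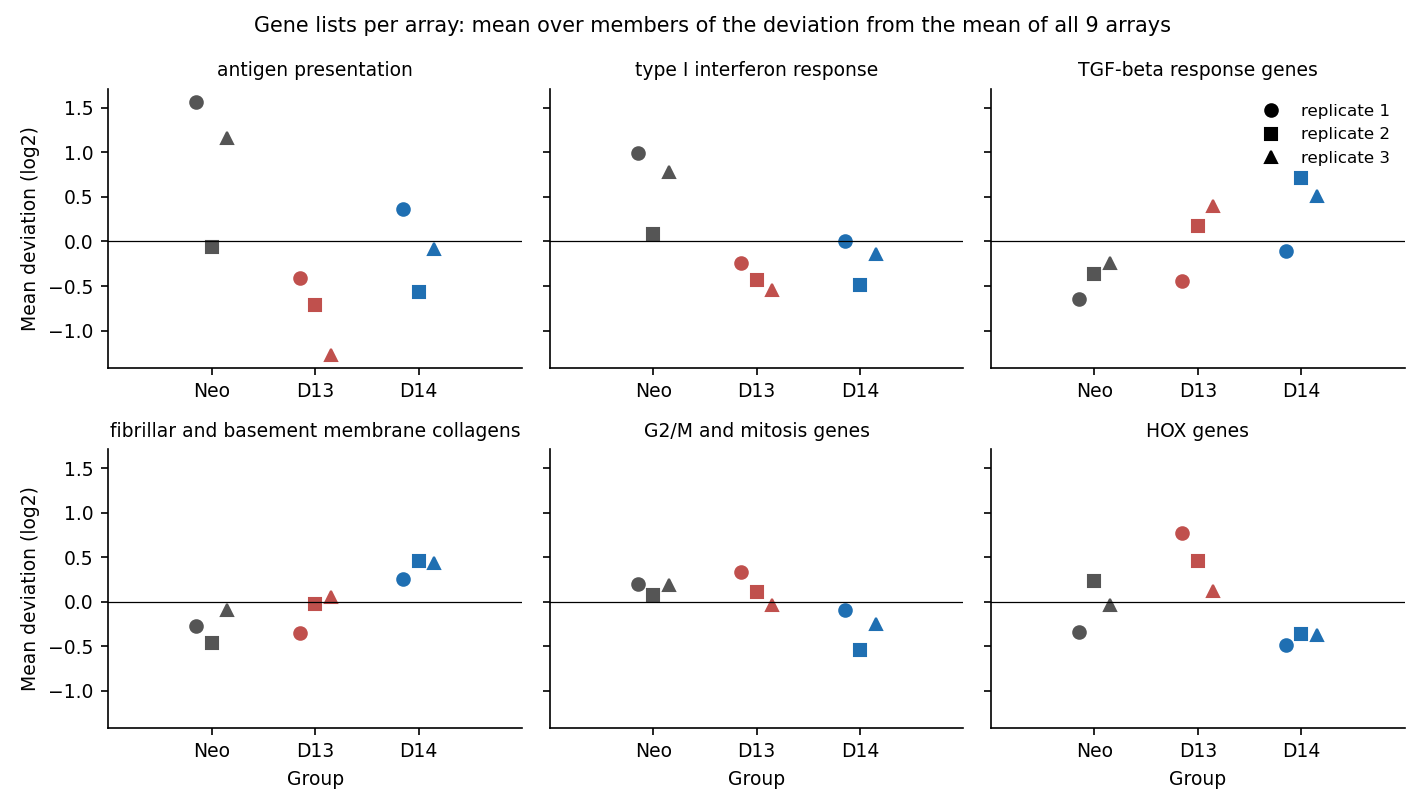
Mean deviation of the members of 6 gene lists from their mean over all 9 arrays (vertical axis, log2) on each array of the 3 groups (horizontal axis), with symbols for the replicate number. Antigen presentation stood at 1.57 and 1.16 on Neo replicates 1 and 3 and at -0.06 on Neo replicate 2, and G2/M and mitosis genes lay lowest on D14 replicate 2, at -0.54.

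Both variants were set against the same Neo arrays, and 27 genes changed in both, 8 higher and 19 lower, with none in opposite directions. The shared higher genes included TNC, NID2, PLAUR, KITLG, VEGFA and ASPN, and the shared lower genes included CYRIA, at -3.12 in D13 and -3.15 in D14, and KLHL4, at -1.99 and -3.32. The 50 simulated data sets with no group difference and mixed arrays, read for this after seeing the data, shared 46 to 106 genes, so the shared controls with such arrays give as many without any effect of the variants. The log2 fold changes correlated across genes at 0.477, against 0.492 to 0.541 in these simulations, and their covariance was 0.153 against 0.152 to 0.176. With 3 control arrays no split of the controls into parts of at least 2 was possible. Without the 3 middle arrays 1 gene, ASPN, was shared, and leaving out 1 array gave 7, 314 and 3 shared genes without Neo replicates 1, 2 and 3, 81, 2 and 19 without D13 replicates 1, 2 and 3, and 15, 8 and 2 without D14 replicates 1, 2 and 3.

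The third comparison set the variants against each other. CRNDE, a long noncoding RNA gene, was higher in D14 by 7.79 ± 1.58 log2 units, at 12.5 in D14, 4.76 in D13 and 9.20 in Neo, and it passed neither comparison against Neo (adjusted p = 0.188 and 0.313). The complement protease gene C1S was higher in D14 by 3.49 ± 0.79 and the immunoproteasome subunit PSMB9 by 3.76 ± 0.67. ANKRD1 fell by 5.92 ± 1.14, TAGLN fell by 3.43 ± 0.59, thrombospondin 1, THBS1, fell by 3.38 ± 0.58, and smooth muscle actin, ACTA2, fell by 1.61 ± 0.37. Of 21 contractile genes 2 fell over all genes and 2 rose and 2 fell adjusted over the list alone, and the list did not pass (camera adjusted p = 0.401). Type I collagen, COL1A1, was higher by 2.35 ± 0.49 on the brighter of its 2 clusters, while the other was at 0.41.

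The genes furthest apart between the variants differed in how each stood to Neo. PSMB9, TESPA1 and MBNL3, higher in D14 by 3.76, at least 3.74 and at least 3.16, had fallen in D13 and lay at -0.51, -0.41 and -0.01 in D14 against Neo. SGIP1, which had risen in D13, was at -3.73 ± 0.68 for D14 against D13 and lay at 0.18 against Neo. FERMT1 and ADGRG1, higher in D14 than in D13 by 3.37 and 3.02, had risen in D14 and lay at -0.31 in D13 against Neo, each. SERINC2 and ADGRG6, at -4.27 and -4.26 for D14 against D13, had fallen in D14 and lay at 0.69 and 0.34 in D13. SPECC1, C1S, CRHBP, OLR1, SLCO4C1 and NEGR1, like CRNDE, passed between the variants and in neither comparison against Neo. The lipoprotein receptor OLR1 was at 2.60 in D13 and -1.87 in D14 against Neo. In total 898 of the 23025 genes changed, 333 higher and 565 lower in D14, with 4549 genes at an unadjusted p below 0.05 and 27.3% of genes without overlap between the groups, against 22.6% to 23.9% in the simulated data sets with mixed arrays. Without the 3 middle arrays 0 genes passed limma, with 2009 at an unadjusted p below 0.05. The 898 genes kept their sign, which was fixed in advance because the groups did not overlap in any of them. Their median absolute log2 fold change went from 1.25 to 1.29 and their median standard error from 0.24 to 0.32 log2 units. Leaving out 1 array gave 941, 1016 and 594 genes without Neo replicates 1, 2 and 3, 539, 4 and 939 without D13 replicates 1, 2 and 3, and 369, 232 and 117 without D14 replicates 1, 2 and 3.

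G2/M and mitosis genes were lower in D14 than in D13. Of 40 members 6 fell and 0 rose, and 10 fell adjusted over the list alone. DLGAP5 fell by 1.50 ± 0.17 log2 units, the spindle protein NUSAP1 fell by 1.29 ± 0.27 and the mitotic kinesin CENPE fell by 1.27 ± 0.28. The median was -0.37, with a camera adjusted p of 3.61e-05 and adjusted p = 0.839 with an estimated correlation. Arrays of 1 variant differed by as much. Over these genes D13 replicate 1 lay above D13 replicate 3, and D14 replicate 1 above D14 replicate 2, by medians of 0.40 each. The replication genes MCM5, MCM6 and MCM2 were higher in D14 by 1.44 ± 0.24, 1.42 ± 0.20 and 1.09 ± 0.17, while the list of 39 DNA replication genes did not pass (0.401), with 3 rising and 1 falling over all genes and 4 rising and 2 falling adjusted over the list alone. The histone genes H2AC4 and H3C7 were higher by 1.34 ± 0.16 and 1.06 ± 0.22 (31 histones, of which 5 rose adjusted over the list alone, 0.217).

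All 16 measured HOX genes had a negative log2 fold change for D14 against D13, with a median of -0.51, although none passed singly, over all genes or adjusted over the list alone. HOXB9 was at -3.83 ± 1.36, a lower limit of the difference since its D14 mean of 3.93 lay below background, and HOXC8 at -1.80 ± 0.50. Camera gave 0.000721, with adjusted p = 0.154 with an estimated correlation. Antigen presentation genes were higher in D14: of 21 members 3 rose, PSMB9, the class II transactivator CIITA by at least 1.33 ± 0.28, from a D13 mean below background (4.18), and the peptide-trimming protease ERAP1 by 1.30 ± 0.23, and 4 rose adjusted over the list alone. Their median was 0.52 (camera adjusted p = 0.00163, and adjusted p = 0.839 with an estimated correlation). The groups overlapped in this list, with D13 replicate 1, at -0.41, above D14 replicate 2, at -0.56. Of 29 hypoxia and glycolysis genes ANKRD37 rose by 0.92 ± 0.22 and the mitophagy receptor BNIP3L fell by 0.80 ± 0.18, the same counts adjusted over the list alone, and camera gave 0.0376 with adjusted p = 0.839 with an estimated correlation. These 4 lists passed camera without the middle arrays as well.

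Matrix and signalling genes differed singly between the variants in lists that did not pass camera. IGFBP7, F3 and ZEB1, which had risen in D13, were lower in D14 than in D13 by log2 fold changes of -3.40 ± 0.40, -2.45 ± 0.30 and -1.45 ± 0.20. PLAU, the urokinase gene, was higher in D14 by 2.50 ± 0.48, MFAP4, of elastic fibres, by 2.18 ± 0.51, COL4A2, of basement membranes, by 1.25 ± 0.23 and ADAMTS2 by 1.30 ± 0.23, while COL11A1 fell by at least 1.31 ± 0.20, to a D14 mean at background (4.33). Camera gave 0.178 for the collagens, 0.921 for the matrix glycoproteins, 0.405 for the matrix proteases and 0.0617 for the TGF-beta response genes. Over all genes 2 collagens rose and 1 fell, 2 glycoproteins rose and 2 fell, 2 proteases rose, and 2 TGF-beta response genes rose and 2 fell. Adjusted over the list alone, these counts were 4 and 1, 4 and 5, 2 and 0, and 3 and 2. WNT5B was higher by 1.91 ± 0.40 and the Wnt receptor FZD7 fell by 1.20 ± 0.27, the same counts adjusted over the list alone (0.854). Of 28 YAP/TAZ and SRF targets 5 fell, ANKRD1 and F3 among them, and adjusted over the list alone 4 rose and 7 fell (0.616). SRD5A1, a steroid 5-alpha reductase, fell by 1.72 ± 0.28, 1 of 14 steroid receptor and androgen response genes in both counts (0.615). The interferon-induced PARP9 was higher by 1.20 ± 0.26 (29 interferon response genes, 1 adjusted over the list alone, 0.178), and NFKBIA, an inhibitor of NF-kappa-B, fell by 1.23 ± 0.28 (30 inflammatory cytokines and chemokines, of which 1 rose and 3 fell adjusted over the list alone, 0.955). CD68 was higher by 2.22 ± 0.31 and the synaptic gene SNAP25 by 1.73 ± 0.33, while the leukocyte, neuronal and endothelial lists were each at an adjusted p of 0.921 and the epithelial list at 0.641.

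Some lists passed in no comparison. Of 12 small leucine-rich proteoglycans ASPN alone passed in D13 and in D14 against Neo, over all genes and adjusted over the list alone, and DCN, the related proteoglycan decorin, was at 1.32 in D13 and -0.10 in D14 against Neo. The chaperone HSP90B1 was higher in D14 than in D13 by 0.98 ± 0.20 log2 units, 1 of 31 genes of the unfolded protein and amino acid responses, whose lowest camera adjusted p over the comparisons was 0.226. The lowest values were 0.703 for 20 genes of cholesterol synthesis, 0.897 for 12 adipogenic genes and 0.11 for 10 osteogenic and chondrogenic genes, and no member of these passed over all genes. SOX9, a chondrogenic transcription factor, was at 1.84 ± 0.66 in D14 against Neo with an adjusted p of 0.187.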

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

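Chosen only after the result was seen were the tests of the share of genes with one array in the middle, of positions on the log2 scale and of the mixture, the spans over 4 and 6 log2 units, the sets of 1 array per group, the differences between outer arrays, and the separate reading of the simulated counts for D14 against D13.

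In each group 1 array, Neo replicate 3, D13 replicate 2 or D14 replicate 3, lay between the other 2, in at least 94.9% of genes that spanned over 2 log2 units, above the 34.4% to 71.1% in sets of 1 array per group; independent samples that differ along one shared axis would do the same, so the share does not decide against them. A gradient of one state on the log2 scale would place the array alike for genes higher at either end, but the median positions differed by 0.280 or more in every group, with the array nearer to whichever end was higher. A candidate explanation is that these arrays measured a mixture of the material behind the other 2. A weighted mean of their linear signals fitted better than any other of the 28 pairs in each group, with weights of 0.49, 0.54 and 0.45 for Neo, D13 and D14. Every other pair held an array of another group, so ordinary replicates could rank the same way, and the rank decides nothing. The deviation of the mean was 0.781 of that of the better single array in Neo, 0.599 in D13 and 0.639 in D14. The bound of 0.8 was also set after. A mean of 2 independent replicates also deviates less than 1 of them, so the ratio alone does not show a mixture, least of all in Neo. In the exon-level table the column with the letter M was most often the middle one in every group, in 43.4% of Neo features spanning over 2 log2 units, 84.1% in D13 and 77.4% in D14; Neo missed the bound of 50% set beforehand for every group, but its share was 68.7% at spans over 4 log2 units and 80.1% over 6, where no other Neo column exceeded 15.8% and 10.7%, so the reading was changed to undecided after the result was seen. A pooled or uncloned culture set beside its components would be a biological reading and a blend of RNA a technical one, and no value here separates them.

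The number of genes that differed between the groups may rest on arrays that are not independent. In 50 simulated data sets with no group difference and 1 mixed array per group, 222 to 431 genes passed for D13 against Neo and 220 to 388 for D14 against Neo. The observed counts were 207 and 247, so counts this large can arise without any effect of the variants. Every draw exceeded the observed 207, so the simulated setting does not reproduce these data in full. For D14 against D13 the highest simulated count was 398 against an observed 898. The simulation drew genes independently, while 68.2% of the variance within Neo, 84.9% within D13 and 81.5% within D14 lay on 1 axis. Its range may therefore be too narrow to measure an excess, and a simulation with assumed settings excludes nothing. Differences between stably transfected cultures that do not depend on the construct also stay open: the range within a group exceeded the group difference in at most 2.67% of called genes, but a call asks for a small range, so this share decides nothing. The overexpressed variant itself stays among the open explanations, and ASPN is the gene that passed without the middle arrays.

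Antigen presentation and interferon response genes were lower in both variants by camera with the preset correlation, though with an estimated correlation neither list passed in D13 (adjusted p = 0.677 and 0.637) or in D14 (0.638 and 0.622), and no member passed singly in D14. Neo replicate 1 stood above Neo replicate 2, and if the high level of that culture, alone and within Neo replicate 3, were the cause, the variants should match Neo replicate 2. Over the 50 genes of both lists the median against Neo replicate 2 was -0.58 in D13, with 39 genes lower, and -0.21 in D14, with 28 lower, both past the bound of -0.2 set beforehand. That bound left out the spread between single arrays, and the outer arrays of a group differed by medians of 0.61 in Neo, 0.40 in D13 and 0.49 in D14 over the same genes, so the reading was changed to undecided after the result was seen. With 1 Neo array as the reference, the high level of 1 Neo culture cannot be told apart from an effect of the variant or another difference between cultures, in D13 as in D14.

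The splits of the 6 arrays of a comparison number 10, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, reached the real count: 207 genes for D13 against Neo, 247 for D14 against Neo and 898 for D14 against D13, with 0 genes as the highest of the other splits. Only the real split keeps each middle array with the outer arrays of its group, which keeps the spread small. The contrast with the other splits therefore decides nothing.

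The D13 and D14 groups differed for 4 lists by the test of D14 against D13 itself: antigen presentation at a median of 0.52, G2/M and mitosis genes at -0.37, hypoxia and glycolysis at 0.24 and HOX genes at -0.51 log2 units. None of the 4 passed with an estimated correlation. In the same order, D13 replicate 1 differed from D13 replicate 3 by medians of 0.77, 0.40, 0.22 and 0.26. D14 replicate 1 differed from D14 replicate 2 by 0.72, 0.40, -0.06 and 0.13. An effect of the variant cannot be told apart here from other differences between the cultures. Features that carry no gene name here were counted as well. Of 42398 transcript clusters without a gene symbol 9 passed for D13 against Neo, 0 for D14 against Neo, with 4189 at an unadjusted p below 0.05, and 103 for D14 against D13. Of 647004 exon-level features 791 passed for D13 against Neo, 619 for D14 against Neo and 11317 for D14 against D13. Exon-level features can lie in the genes tested above, so these counts are not signal from other genes.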

How the results depend on the processing

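Protein-coding genes alone and the fit without the middle array of each group were tests chosen only after the result was seen. The ASPN difference from Neo passed under every alternative run. Counts of genes stayed within 1.5 times of the main counts with quantile normalization (242, 288 and 821 for D13 against Neo, D14 against Neo and D14 against D13), median centring, the other filters, the other choices of clusters, the trended robust prior, a 2-fold minimum and protein-coding genes alone, and no result changed direction across the threshold. Fitting only the 2 groups compared gave 30 genes for D13 against Neo and 6 shared by both variants, with fewer arrays to estimate the spread. An adjusted p below 0.01 gave 12, 11 and 99 genes and 2 shared. Array weights, whose estimation did not converge, gave 3796, 2370 and 13856 genes, 775 shared, and ASPN past the threshold for D14 against D13 at 0.36; the cause was not tested. Without the middle array of each group, with fewer samples, 1, 1 and 0 genes passed, 1 was shared, and 2, 6 and 4 lists passed. With a replicate block 126, 274 and 652 genes passed and 32 were shared; same-numbered arrays had correlations of deviations from -0.055 to 0.319, against -0.305 to 0.290 for other pairs, so the numbers did not pair the samples.

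Leaving out 1 array gave 3 to 920 genes for D13 against Neo, without D13 replicate 2 and without Neo replicate 2. For D14 against Neo the range was 8 to 733, without D14 replicate 3 and without Neo replicate 2, and for D14 against D13 it was 4 to 1016, without D13 replicate 2 and without Neo replicate 2. Shared genes ran from 2 to 314. Lists numbered 3 to 10, 7 to 11 and 3 to 5. Lists numbered 0, 0 and 0 with an estimated correlation and 0, 0 and 1 with fry; for D14 against D13 they numbered 7 with no filter and 7 with the trended robust prior, and the cause was not tested. Of the 114 calls of named genes other than ASPN 113 held with median centring, 108 with quantile normalization, 100 with the trended robust prior, 77 with only the 2 groups compared, 8 to 108 when 1 array was left out and 0 without the middle arrays. Gene-level values from the second deposited table were not run, since it holds exon-level values, and testing every cluster on its own gives no list results. Background control probes averaged 4.32 to 4.48 log2 units per array, so the Neo level of ASPN, 4.70, lies near background and its fold change is limited by it.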

Other observations

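The values of single arrays below were chosen only after they were seen, and no tests were run on them.

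D13 replicate 1 lay below D13 replicate 3 in the mesenchymal transcription factor PRRX1, at -9.29 log2 units, the gelatinase MMP2 (-8.03), the proteoglycan versican, VCAN (-7.70), the fibroblast activation protein FAP (-7.58) and periostin, POSTN (-7.39). It lay above in the desmosomal plakophilin PKP2 (7.74), TPD52 (7.74), the simple-epithelial keratin KRT18 (6.61) and the apical transport protein MAL2 (6.47). PKP2, TPD52 and KRT18 were below every Neo array on D13 replicate 3, at 7.39, 6.10 and 6.73 against at least 14.02, 11.75 and 11.41. PRRX1, VCAN and POSTN were above every Neo array there, at 14.07, 12.30 and 16.64 against at most 5.78, 5.44 and 13.76. MMP2 was below every Neo array on D13 replicate 1, at 8.76 against at least 14.27. On D13 replicate 3 it was above them, at 16.79 against at most 15.82. FAP, MAL2, PKP2, TPD52, PRRX1 and VCAN also left the Neo range on both of these D13 arrays. Over lists, D13 replicate 1 stood below replicate 3 by a median of -1.07 for matrix glycoproteins and -0.71 for matrix proteases, and above it by 0.77 for antigen presentation, while the median of the mesenchymal stromal markers was -0.38 and that of the prostate epithelial markers 0.34, with 4 of 11 higher by over 1 log2 unit and 0 lower; their mean deviation was lowest on D13 replicate 3, at -0.92. D14 replicate 1 lay above D14 replicate 2 in BMP4 (6.10) and PKP2 (5.35), and below it in the growth factor receptor PDGFRA (-7.88) and in the cytokine IL33 (-7.22). Its median was lower for TGF-beta response genes (-0.73) and mesenchymal stromal markers (-0.24) and higher for antigen presentation (0.72).

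Neo replicate 1 lay above Neo replicate 2 in the noncoding RNA gene CRNDE (7.47), the arginine transporter SLC7A3 (7.47) and the chemokine CCL2 (at least 6.95), and below it in POSTN (-6.53), the transcription factor TFAP2A (-5.55) and HOXB9 (-4.23); CCL2 on Neo replicate 2 and HOXB9 on Neo replicate 1 lay below background, so their differences are lower limits. Over lists it stood above by a median of 1.23 for antigen presentation, which also differed within D13 and D14, 1.12 for cholesterol synthesis, 1.01 for NRF2 targets and metallothioneins and 0.62 for the respiratory chain, and below by -1.05 for receptor tyrosine kinase and MAPK feedback genes. Of 22 p53 targets 11 were higher by over 1 log2 unit and 0 lower by as much. CRNDE, the named gene with the largest difference between D14 and D13, thus differed nearly as much between control arrays.

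At exon level, 13 features were higher by over 4 log2 units in both variants. Among them JUC0900061508.hg.1 was at 10.69 in D13 and 11.35 in D14, and JUC0900061507.hg.1 at 10.28 and 10.80, against Neo. The tables used here do not pair these features with genes.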
